A study of Mus musculus with 12 samples.

How the data were processed

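Gene expression was measured on Affymetrix arrays in NIH3T3 cells, an immortalised line of mouse fibroblasts. The cells received a transfection reagent alone (Mock), an siRNA named for EGFP (sirEGFP), or 1 of 2 siRNAs against UBF, the nucleolar transcription factor encoded by Ubtf. Each siRNA was used at 40 nM and RNA was taken 48 h after transfection, per the labels. From 100 ng of total RNA, 2.5 ug of labelled cDNA was made for each array, per the labels' protocols. Each of the 4 groups holds 3 arrays, which the series' design text calls biological replicates, and the groups share the replicate numbers 1 to 3.

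The deposited values are log2 expression values, 1 per probe set and array, for 35512 probe sets on 12 arrays. The scale was read from the values themselves, since the summary method, background correction and normalization are not given in the sources used here. The submitters' processing notes name limma, with no step and no version. Array medians lay between 5.38 and 5.54, so the deposited values were used as they stood. Centring each array on its median and quantile normalization were tried as alternatives. Signal over background could not be judged from these values, and the number of arrays limits the precision.

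Probe sets were named through the platform annotation. Of the 35512 probe sets, 21789 carried 1 gene symbol, 1621 carried several and 12102 carried none in the annotation used. Symbols were checked by Entrez identifier against RefSeq gene names of assembly GRCm38.p6, where 21698 probe sets matched and the other 91 kept their annotated symbol. No coordinates were used. Probe sets with several genes were not named. For the 999 genes with several probe sets, the one with the highest mean over the 12 arrays was taken, which left 19938 genes.

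Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 1 coefficient for each of the 4 groups and all 12 arrays in the fit, which gave 8 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 19938 genes, and a gene was called at an adjusted p under 0.05. Changes are differences of log2 means with limma's moderated standard error (SE). The comparisons were each siRNA against sirEGFP, the mean of both against sirEGFP, each against Mock, sirEGFP against Mock, and the siRNAs against each other. The test of the difference between the siRNAs for gene lists was added after the data had been seen.

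The tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined, except for the following. The limit for the correlation of the siRNAs was changed from a fixed value to an SD after results had been seen. The weighing of explanations for list patterns by both the preset and the estimated correlation was also set then, as were the additions stated below. The rule named Ubtf. It then took genes called with both siRNAs against sirEGFP in the same direction whose 6 knockdown arrays all lay beyond all 6 control arrays, the 12 highest and the 12 lowest by mean change. From each list it took up to 4 members with the smallest p in the mean comparison, whether or not they passed. From the comparison between the siRNAs, and from sirEGFP against Mock, it took the 5 highest and 5 lowest changes among genes called. The same number was taken from genes called with 1 siRNA where the difference between the siRNAs was itself called. Predicted and clone-named genes were passed over in the ranked parts.

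The 25 lists covered Pol I machinery, Pol II and Pol III subunits, replication-dependent histones, replication-independent histones, histone mRNA transcription and processing, cytosolic ribosomal proteins, ribosome biogenesis factors, small nucleolar RNAs (snoRNAs) and translation factors. They also covered p53 targets, DNA replication and G1/S, G2/M and mitosis, DNA damage response and repair, interferon-stimulated genes, inflammatory and NF-kB targets, extracellular matrix and cholesterol synthesis. The remaining lists held genes of the integrated stress response, endoplasmic reticulum chaperones, glycolysis and hypoxia, and markers of adipocytes, skeletal muscle, smooth muscle and myofibroblasts, epithelium and macrophages. A list needed at least 5 measured members. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists within a comparison, with an estimated correlation as the stricter check and with fry. Fry asks whether a list's genes move one way on balance, without comparing them with other genes.

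The comparisons of the 2 siRNAs with sirEGFP share their 3 control arrays. Overlaps and correlations were therefore set beside 100 simulations of unchanged groups with shared controls, and beside a version in which the control arrays were not shared. The simulations drew each gene and array independently. On simulated log2 data with the means and spreads of these 19938 genes, 100 genes changed by 0.58 and 100 changed by 1 on the log2 scale. For the mean of both siRNAs against sirEGFP, 73% and 98% of these were called, with 11 false calls. For oligo 1 the shares were 47% and 96% with 11 false calls, and for oligo 2 they were 46% and 97% with 5. Between sirEGFP and Mock no change was simulated, and limma called 0 genes, with 972 at an unadjusted p under 0.05. A shift of 0.3 in 1 simulated list was called, with 0 calls among the other lists. These simulated data also drew genes independently, so they do not show how often lists whose genes move together are called falsely.

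Alternatives changed the scaling, the filter on dim genes, the rule for several probe sets, the probe sets tested, the replicate number as a block, the variance model, array weights, the arrays in the fit, the control group, the threshold and the correlation within lists. Each array was also left out in turn. After the data had been seen, the main axis of spread within groups was added as a covariate, and the 3 arrays at its ends were left out together. Each array was also left out in turn for the list calls that hold with an estimated correlation, and for 4 lists and their members called with 1 siRNA, likewise after the data had been seen. For the correlation of the siRNAs, which has no test, a move beyond 0.0598, the SD of the correlations with 1 array left out, was counted as a change.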

Results

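Expression was measured on 12 arrays of NIH3T3 mouse fibroblasts, with 3 arrays each for Mock, sirEGFP, oligo 1 and oligo 2, the last 2 being independent siRNAs against UBF. UBF, encoded by Ubtf, is a nucleolar protein that acts with RNA polymerase I on ribosomal RNA genes. Array medians lay between 5.38 and 5.54 on the log2 scale. Arrays of a group correlated at Pearson's r of 0.980 to 0.994 across genes, against 0.975 to 0.994 for arrays of different groups. The design asks what changes in the transcriptome when Ubtf is silenced, with an unrelated siRNA and reagent alone as controls.

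The Ubtf transcript was lower on all 6 knockdown arrays than on all 6 control arrays. On the log2 scale it stood at 8.54, 8.63 and 8.41 on the Mock arrays, 8.68, 8.31 and 8.04 with sirEGFP, 7.998, 7.74 and 7.64 with oligo 1, and 7.90, 7.83 and 7.49 with oligo 2. The mean level was 8.53 ± 0.11 (SD, n = 3) in Mock, 8.34 ± 0.32 in sirEGFP, 7.79 ± 0.19 with oligo 1 and 7.74 ± 0.22 with oligo 2. The knockdown arrays lay at -0.67 relative to the controls, with an exact permutation p = 0.00216 (two-sided, 924 splits of the 12 arrays). Against sirEGFP the log2 change of Ubtf was -0.55 ± 0.17 (SE) with oligo 1 and -0.61 ± 0.17 with oligo 2, which is 31.9% and 34.3% lower. Neither passed limma's test over all genes (adjusted p = 0.107 and 0.0771), nor did the mean of both at -0.58 ± 0.14 (adjusted p = 0.0526). Against Mock, Ubtf fell by 0.74 with oligo 1 (adjusted p = 0.0252) and by 0.79 with oligo 2 (adjusted p = 0.0146). The siRNAs differed in Ubtf by 0.052 (95% interval -0.30 to 0.40). Without sirEGFP 3, the control array with the lowest Ubtf level, oligo 2 against sirEGFP passed (log2 change -0.76, adjusted p = 0.0490), as did the mean of both (-0.73, adjusted p = 0.0432). Without oligo 1 array 1 the mean also passed (-0.63, adjusted p = 0.0405). Both siRNAs passed with array weights (-0.63 and -0.61, adjusted p = 0.00178 and 0.0204) and against the mean of Mock and sirEGFP (-0.64 and -0.70, adjusted p = 0.0185 and 0.0114). The weighted oligo 1 value rests mostly on its array 3, with a weight of 8.92 against 0.44 and 0.42 for arrays 1 and 2. Both siRNAs also passed with the within-group axis as a covariate, chosen after seeing the data (adjusted p = 0.0119 and 0.00790). By construction that covariate lowers the spread and leaves the changes as they are, so these smaller p-values add no support. The mean of both passed under quantile normalization (adjusted p = 0.0435) and without the dimmest genes (0.0456 and 0.0396). Over all alternatives the adjusted p of Ubtf lay between 0.00178 and 0.326 with oligo 1 and between 0.00790 and 0.2996 with oligo 2.

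**Figure D1:**
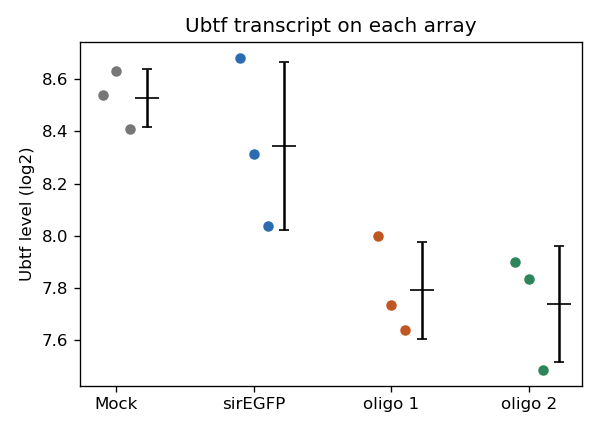
Ubtf level on the log2 scale (y axis) on each array of the 4 groups (x axis); points are arrays, and the black marks give the mean and SD of 3 arrays. The knockdown arrays reach at most 7.998, and the lowest control array, in sirEGFP, lies at 8.04.

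Genes shared by both siRNAs were ranked where all 6 knockdown arrays lay beyond all 6 controls, with predicted and clone-named genes passed over. Among these, Txnip, an inhibitor of thioredoxin, rose most, by 1.99 ± 0.17 on the log2 scale (SE, n = 6 against 3), or 3.97-fold (limma adjusted p = 6.08e-05). Cp, the copper carrier ceruloplasmin, rose by 1.80 and the histone gene H2bc4 by 1.70. Ppargc1a, a coactivator of mitochondrial gene expression, rose 2.83-fold. Mgst1, a microsomal glutathione transferase, rose by 1.31, Plscr2 by 1.15, Lxn by 1.13 and Lif, a cytokine of the IL-6 family, by 1.07. Vcan, which encodes the matrix proteoglycan versican, rose by 0.99, Wdr19 by 0.97, the sphingosine phosphate lyase gene Sgpl1 by 0.96 and N4bp2 by 0.92. The SE of these 12 changes and of the 12 decreases that follow lay between 0.10 and 0.20, and each had all 6 knockdown arrays beyond all 6 controls. Lif no longer passed without sirEGFP 2 (adjusted p = 0.0506).

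Slc4a4, a sodium bicarbonate cotransporter, had the lowest change among the shared genes ranked in the same way, at -1.45 ± 0.12 (limma adjusted p = 5.67e-05). The snoRNAs Snora73a, Snora73b and Snord52 fell by 1.23, 1.21 and 1.08. Fancb and Mre11a, both of DNA repair, fell by 1.11 and 0.80, and Idi1, an enzyme of isoprenoid synthesis, fell by 1.08. Spdl1, which acts at kinetochores, and Orc2, of the origin recognition complex, fell by 0.73 and 0.64. Ppp3cb, a catalytic subunit of calcineurin, fell by 0.73, Cmss1 by 0.72 and B3galnt2 by 0.67. Without sirEGFP 2 or sirEGFP 3 the calls were lost for Spdl1 (adjusted p = 0.153 and 0.152), Orc2 (0.124 and 0.0954) and B3galnt2 (0.0518 and 0.0647). Spdl1 was also lost without oligo 2 array 1 (0.0509) or array 3 (0.0505), and Snord52 without sirEGFP 3 (0.114).

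Over all genes, limma called 493 with oligo 1 against sirEGFP (208 higher, 285 lower), 451 with oligo 2 (303 higher, 148 lower) and 385 with the mean of both (241 higher, 144 lower). The share of higher calls with oligo 1 (42.2%) was not stable, and higher calls outnumbered lower ones without sirEGFP 1 (52.6%), without oligo 1 array 2 (52.5%), without the 3 arrays at the ends of the main axis of spread within groups (57.6%), with that axis as a covariate (59.9%) and with array weights (51.8%). Of the calls with oligo 1, oligo 2 and the mean, 66, 86 and 33 changed at least 2-fold. Both siRNAs called 80 genes in the same direction (60 higher, 20 lower) and 2 in opposite directions, against 5.28 same-direction genes for independent lists of these sizes and 0 in simulated unchanged groups with shared controls. That simulation draws each gene and array independently, while the main axis held 41.5% of the variance within groups. In fits of the 9 arrays of these groups alone, the real grouping gave 54 shared genes and the highest of the other regroupings drawn at random 66. Over all 19938 genes, 423 had all 6 knockdown arrays beyond all 6 controls, a separation that chance gives in 0.216% of genes. With no control array shared (oligo 1 against sirEGFP, oligo 2 against Mock), 82 genes were called in the same direction and 9 in opposite ones, against 9.86 for independent lists. Log2 changes of the siRNAs correlated across genes at r = 0.463, against 0.499 in the simulation, and genes are not independent replicates. Their covariance was 0.0273 against 0.0123 simulated, a difference of 0.0150, and without shared controls it was 0.00997 (r = 0.161). Part of the shared calls and of the correlation may come from the sirEGFP arrays that both comparisons use, and these were too few to be split, since 1 part would keep fewer than 2 arrays.

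These counts moved with single arrays. The count for oligo 1 was 155 and 218 without sirEGFP 2 and 3, and 260, 863 and 209 without oligo 1 arrays 1, 2 and 3. For oligo 2 it was 198 and 200 without sirEGFP 2 and 3, and 230, 237 and 218 without oligo 2 arrays 1, 2 and 3. The mean of both gave 108 and 116 without sirEGFP 2 and 3, 722 and 225 without oligo 1 arrays 2 and 3, and 220 and 226 without oligo 2 arrays 1 and 3. The 80 shared genes became 20 and 23 without sirEGFP 2 and 3, 52, 140 and 37 without oligo 1 arrays 1, 2 and 3, and 44, 53 and 46 without oligo 2 arrays 1, 2 and 3. The 82 became 46, 42 and 53 without Mock 1, 2 and 3, 31 and 42 without sirEGFP 2 and 3, 34 without oligo 1 array 3, and 44, 43 and 37 without oligo 2 arrays 1, 2 and 3. The correlation was 0.623 without sirEGFP 1, 0.376 without oligo 1 array 1 and 0.393 without oligo 2 array 1. Oligo 1 arrays 2 and 1 and sirEGFP 1 stood apart at the ends of the main axis of spread within groups, and without these 3 arrays the counts were 255 for oligo 1, 1049 for oligo 2 and 793 for the mean of both.

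**Figure D2:**
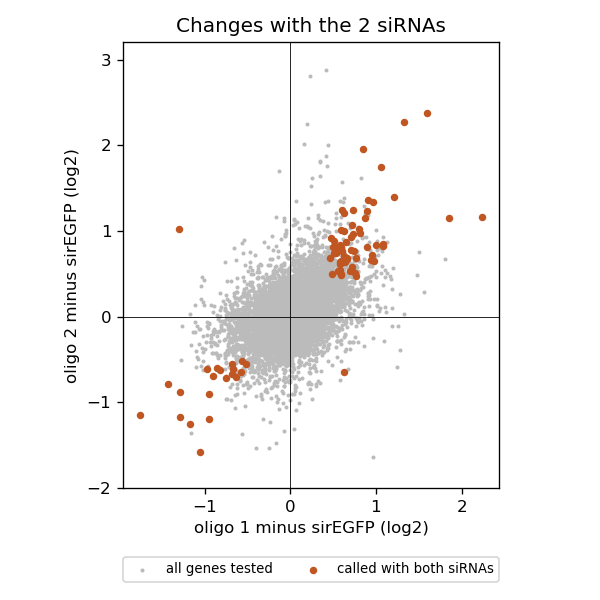
Log2 change of each of 19938 genes with oligo 1 (x axis) and oligo 2 (y axis) against sirEGFP; orange points are genes called with both siRNAs. Of the orange points, 80 lie in the quadrants of equal sign and 2, U90926 and Dtna, the latter named after its values were seen, in those of opposite sign.

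Targets of p53 were higher with both siRNAs, with a list median of 0.32 for the mean of both against sirEGFP, 0.22 with oligo 1 and 0.42 with oligo 2. Of 28 measured members, 6 rose and 0 fell in the mean comparison, or 10 and 0 adjusted over the list alone. Abhd4 rose by 0.84, the death receptor Fas by 0.88, Mdm2, the ubiquitin ligase that limits p53, by 0.63, and Zmat3 by 0.58. The list was called with camera (adjusted p = 1.5e-08) and also held at adjusted p = 0.0304 with an estimated correlation. With oligo 1 alone the call (adjusted p = 0.00113) was lost at adjusted p = 0.0805 with an estimated correlation, and with oligo 2 alone it held (0.0158). With an estimated correlation, the call of the mean was lost without Mock 2 (adjusted p = 0.0531), sirEGFP 1 (0.134), sirEGFP 2 (0.0765), oligo 1 array 3 (0.0602) or oligo 2 array 3 (0.0535), and that of oligo 2 without sirEGFP 1 (0.0640). The members' mean level lay between -0.022 and 0.32 on the knockdown arrays, between -0.22 and -0.10 with sirEGFP and between -0.25 and -0.16 in Mock. Fas was called with oligo 2 (1.52) and not with oligo 1 (0.24), a difference that was itself called (adjusted p = 0.00145). Without sirEGFP 2 the calls of Abhd4 (adjusted p = 0.0679) and Fas (0.116) were lost, and Abhd4 was also lost without sirEGFP 3 (0.101). Mdm2 was lost without every array but Mock 2, oligo 1 array 2 and oligo 2 array 2 (0.0524 to 0.273), and Zmat3 without every array but Mock 3 and oligo 1 array 2 (0.0550 to 0.283).

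Inflammatory and NF-kB targets were higher, with a median of 0.15, 5 of 20 members called higher and 0 lower (6 and 0 adjusted over the list alone). The chemokine genes Ccl7 and Ccl2 both rose by 1.40, Il6 rose by 1.23 and Lif by 1.07. The list's camera call (adjusted p = 0.000122) was lost at adjusted p = 0.0910 with an estimated correlation. Among interferon-stimulated genes 3 of 37 rose and 0 fell, and as many adjusted over the list alone, at a median of 0.053. These were Ifitm3 (0.66), the RNA sensor Ddx58 (0.64) and the peptide transporter Tap1 (0.64), while Eif2ak2 stood at 0.37 (adjusted p = 0.153). That list passed camera (adjusted p = 0.00498), with adjusted p = 0.159 with an estimated correlation. Without the 3 arrays at the ends of the within-group axis the interferon call was lost (adjusted p = 0.107) and its median turned to -0.0072. Lif was not called without sirEGFP 2 (0.0506), nor Tap1 without sirEGFP 2 or 3 (0.162 and 0.139).

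Extracellular matrix genes had a median of 0.22, with 2 of 31 called higher and 0 lower, or 3 and 1 adjusted over the list alone. Tnc, which encodes tenascin C, rose by 1.52, with 2.81 for oligo 2 and 0.23, not called, for oligo 1, and Col6a3 by 0.50, while Fn1 (0.69, adjusted p = 0.0767) and Ccn2 (-0.73, adjusted p = 0.0612) did not pass. The matrix list was called at adjusted p = 0.000468, with adjusted p = 0.316 with an estimated correlation, and against Mock its call was lost (adjusted p = 0.635). Col6a3 was lost without every array but sirEGFP 1 and oligo 1 array 2 (0.0524 to 0.276). Fn1 passed without sirEGFP 1 (0.0261) or oligo 1 array 2 (0.00802), and Ccn2 without oligo 1 array 1 (0.0184).

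SnoRNAs, which guide modification and processing of ribosomal RNA, were lower, with a list median of -0.46 for the mean of both, -0.34 with oligo 1 and -0.64 with oligo 2. Of 51 measured, 4 fell and 0 rose over all genes, and 20 fell adjusted over the list alone. Besides Snora73a, Snora73b and Snord52 this was Snora74a, at -0.78. The camera call (adjusted p = 2.65e-17) was lost at adjusted p = 0.141 with an estimated correlation, which was 0.394 between the members. With oligo 1 and oligo 2 alone the calls (adjusted p = 2.18e-09 and 2.95e-18) were lost at adjusted p = 0.273 and 0.205 with an estimated correlation. A set of 17 other small non-coding RNAs had a median of -0.11, and their mean level lay between -0.20 and -0.011 on the knockdown arrays and between 0.0043 and 0.23 on the control arrays. It was highest on Mock 1 and lowest on oligo 2 array 2, as was that of the snoRNAs (0.66 and -0.68). The snoRNAs overlapped between knockdown and control arrays, since their mean level on oligo 1 array 2 (-0.00037) lay above Mock 2 (-0.021) and sirEGFP 2 (-0.0034). Of the other small RNAs, Rny3 stood at -0.76 (adjusted p = 0.397), Scarna8 at -0.58 (0.290) and Rny1 at -0.46 (0.202). The 20 host genes of snoRNAs had a median of -0.049, and Snhg5 among them fell by 0.66 (adjusted p = 0.00848), a call lost without sirEGFP 3 (0.0702). Rny1, Rny3, Scarna8 and Snhg5 were named after their values were seen. Snord52 was lost without sirEGFP 3 (adjusted p = 0.114). Snora74a was lost without Mock 1 (0.0536), Mock 3 (0.0620), sirEGFP 2 (0.152), sirEGFP 3 (0.303), oligo 1 arrays 1 and 3 (0.0759 and 0.0630) and oligo 2 arrays 1, 2 and 3 (0.0863, 0.101 and 0.0791).

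Ribosome biogenesis factors had a median of -0.093, and 1 of 55 fell (6 adjusted over the list alone, 0 higher), Wdr12 at -0.46. Utp15 (-0.39, adjusted p = 0.0503), Gar1 (-0.38, 0.0628) and Ddx21 (-0.35, 0.0930) did not pass. Their list was called at adjusted p = 2.78e-05, with adjusted p = 0.143 with an estimated correlation. Cytosolic ribosomal proteins had a median of -0.066, and limma called 0 of 55 members, also adjusted over the list alone, with 6 at an unadjusted p under 0.05, all lower. The lowest p-values belonged to Rpl30 (-0.49, adjusted p = 0.128), Rps20 (-0.25, 0.215), Rps13 (-0.25, 0.244) and Rpl22 (-0.27, 0.253). The list test gave adjusted p = 0.000229, with adjusted p = 0.0910 with an estimated correlation. Without sirEGFP 1 the biogenesis call was lost (adjusted p = 0.0581), and without the 3 arrays at the axis ends the biogenesis (0.377) and ribosomal protein calls (0.0869) were lost. Wdr12 was lost without every array but oligo 1 array 2 (0.0582 to 0.230), and without that array Gar1 (0.0283) and Rpl30 (0.0270) passed.

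Genes of the cell cycle were lower in the mean comparison and with oligo 1. The G2/M list had a median of -0.28 for the mean of both, -0.49 with oligo 1 and -0.034 with oligo 2, and 7 of 36 members fell in the mean comparison (15 adjusted over the list alone, 0 higher). With oligo 1, 14 fell (24 adjusted over the list alone), and with oligo 2 limma called 0 in either way, with 6 at an unadjusted p under 0.05 (1 higher, 5 lower). Prc1, of the central spindle, fell by 0.78, Ect2 by 0.71, Tpx2, of spindle assembly, by 0.59 and Birc5, which encodes survivin, by 0.55. The G1/S list stood at -0.18 for the mean, -0.52 with oligo 1 and 0.048 with oligo 2, with 2 of 36 members lower in the mean (6 adjusted over the list alone) and 10 with oligo 1 (19 adjusted over the list alone). With oligo 2 limma called 0 of these, with 5 at an unadjusted p under 0.05 (3 higher, 2 lower). Gins1, of the replicative helicase, fell by 0.63 and Pola1, of DNA polymerase alpha, by 0.60, while Rrm1 (-0.37, adjusted p = 0.0965) and Dtl (-0.33, 0.128) did not pass. DNA damage genes had medians of -0.11, -0.31 and 0.079 in the same order, with 4 of 31 lower (7 adjusted over the list alone) and 0 higher. Mre11a (-0.80), the helicase gene Blm (-0.54), the checkpoint kinase gene Chek1 (-0.51) and Topbp1 (-0.40) fell. In the mean comparison camera called G2/M (adjusted p = 5.61e-15), G1/S (1.44e-06) and DNA damage (4.34e-05), with adjusted p = 0.0910, 0.141 and 0.141 with an estimated correlation. With oligo 1 all of these held, at adjusted p = 0.0307, 0.0324 and 0.0324 with an estimated correlation. These were lost without sirEGFP 1 (0.168 each), oligo 1 array 2 (0.105, 0.105 and 0.108) or oligo 2 array 3 (0.0502 each). The G1/S and DNA damage lists were also lost without Mock 1 (0.0542 and 0.0548), and DNA damage without oligo 1 array 1 (0.0664).

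The difference between the siRNAs was itself called for these cell cycle and DNA damage lists, with medians of -0.60 for G1/S, -0.45 for G2/M and -0.33 for DNA damage in oligo 1 against oligo 2. Members lower with oligo 1 numbered 15 of 36 in G1/S (25 adjusted over the list alone), 10 of 36 in G2/M (21) and 10 of 31 in DNA damage (13, with 1 higher). Camera gave adjusted p = 9.34e-21, 5.2e-21 and 8.21e-13, and each list held at adjusted p = 0.0280 with an estimated correlation. Each was then lost without sirEGFP 1 (0.0609), oligo 1 array 2 (0.106), oligo 1 array 3 (0.0509), oligo 2 array 1 (0.0645) or oligo 2 array 3 (0.0512), G2/M also without oligo 2 array 2 (0.0542) and DNA damage without oligo 1 array 1 (0.0550). Tpx2 (-1.04), Chek1 (-0.87) and Topbp1 (-0.83) were among the members called lower with oligo 1 than with oligo 2. In the mean comparison, the G1/S (adjusted p = 0.117) and DNA damage calls (0.0617) were lost without the 3 arrays at the axis ends. Without sirEGFP 2 the calls were lost for Ect2 (0.116), Tpx2 (0.105), Birc5 (0.0530), Blm (0.121) and Chek1 (0.197), and without sirEGFP 3 for Ect2 (0.0841), Blm (0.105) and Chek1 (0.145). Chek1 was also lost without oligo 2 arrays 1 and 2 (0.0515 and 0.0503). Pola1 was lost without every array but Mock 2, Mock 3 and oligo 1 array 2 (0.0578 to 0.202), and Topbp1 without every array but Mock 3, oligo 1 array 2 and oligo 2 array 2 (0.0520 to 0.202).

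Cholesterol synthesis genes were lower with both siRNAs, at a median of -0.32 for the mean, -0.41 with oligo 1 and -0.26 with oligo 2. Of 20 members, 3 fell and 0 rose (7 and 0 adjusted over the list alone): Idi1 (-1.08), Hsd17b7 (-0.63) and the sterol carrier gene Stard4 (-0.62). Hmgcs1 stood at -0.40 (adjusted p = 0.0528). The camera call (adjusted p = 3.93e-11) was lost at adjusted p = 0.0910 with an estimated correlation. So were those with oligo 1 (4.35e-11) and oligo 2 (2.24e-06), at adjusted p = 0.0805 and 0.211 with an estimated correlation. Hsd17b7 was lost without sirEGFP 1, 2 and 3 (adjusted p = 0.0747, 0.198 and 0.0608), oligo 1 array 3 (0.0620) and oligo 2 arrays 2 and 3 (0.0643 and 0.0747).

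Replication-dependent histones had a median of -0.21, yet the members called in the mean were H2bc4 (1.70) and H1f2 (0.63), both higher, with 0 of 24 lower. Adjusted over the list alone, 2 were higher and 5 lower. H2bc3 (-0.47, adjusted p = 0.0524) and H4c4 (-0.60, 0.0671) did not pass. The histone list was called at adjusted p = 0.00241, with adjusted p = 0.173 with an estimated correlation. It was not called without sirEGFP 1 (adjusted p = 0.0546) or without the 3 arrays at the axis ends (0.0732). With oligo 1 the list was also called (median -0.25, adjusted p = 0.000442, and adjusted p = 0.157 with an estimated correlation), with 4 of 24 lower and 2 higher, or 8 and 3 adjusted over the list alone. H4c4 (-1.05), H4c6 (-0.72), H2bc3 (-0.60) and H4c14 (-0.58) fell with oligo 1, of which H4c6 and H4c14 were named after their values were seen. With oligo 2 the list was not called (median -0.13, adjusted p = 0.224), and limma called 1 member higher and 0 lower, with 2 higher and 1 lower at an unadjusted p under 0.05. The difference between the siRNAs was not called for the list (adjusted p = 0.0899). With oligo 1, H2bc3 was lost without sirEGFP 1, 2 and 3 (0.0609, 0.137 and 0.0525) and oligo 1 arrays 2 and 3 (0.0544 and 0.132), and H4c14 without sirEGFP 1, 2 and 3 (0.0627, 0.101 and 0.108) and oligo 1 arrays 1 and 3 (0.0866 and 0.146). H4c6 was lost there without Mock 1 (0.0508), sirEGFP 1, 2 and 3 (0.0771, 0.118 and 0.0735) and oligo 1 arrays 1, 2 and 3 (0.0868, 0.0645 and 0.0527). Without the 3 arrays at the axis ends none of these decreases passed with oligo 1 (0.0912 to 0.446), nor did H1f2 (0.292). In the mean comparison H1f2 was lost without sirEGFP 1 and 2 (0.0865 and 0.116) and oligo 2 arrays 1 and 3 (0.0504 and 0.0623), while H2bc3 passed without oligo 1 array 1 (0.0256) and H4c4 without Mock 3 (0.0444).

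Pol I machinery, the partners of UBF, had a median of -0.097, and limma called 0 of 15 members, also adjusted over the list alone, with 3 at an unadjusted p under 0.05, all lower (camera adjusted p = 0.149). Its leading members were Twistnb (-0.40, adjusted p = 0.230), Taf1b (-0.32, 0.459), Rrn3 (-0.26, 0.344) and Polr1d (-0.21, 0.333). Among Pol II and Pol III subunits, at a median of -0.020 (camera adjusted p = 0.154), Polr3g (-0.52) and Polr2h (-0.45) fell, 2 of 22, with as many adjusted over the list alone. Polr3f (-0.37, adjusted p = 0.169) and Polr2d (-0.28, 0.246) did not pass. Both lists passed under quantile normalization (0.0489 each, medians -0.12 and -0.025) and without sirEGFP 3 (0.0283 and 0.0152). Pol I machinery also passed without oligo 1 array 3 (0.0414), and the subunits passed without oligo 2 array 1 (0.0318), against Mock (0.0275) and against the mean of both controls (0.0391). Polr3g and Polr2h were each lost without every array but oligo 1 array 2 (0.0581 to 0.152 and 0.0527 to 0.211).

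For histone mRNA transcription and processing (median -0.12, adjusted p = 0.143), Cpsf3 rose by 0.56, 1 of 13 members, and adjusted over the list alone 1 was higher and 2 lower. Cpsf2 (-0.46, adjusted p = 0.0713), Eri1 (-0.40, 0.0801) and Slbp (-0.28, 0.326) did not pass. Cpsf3 was lost without Mock 1 (0.0504), sirEGFP 1, 2 and 3 (0.0613, 0.0519 and 0.220), oligo 1 array 3 (0.0718) and oligo 2 arrays 1 and 2 (0.0631 and 0.0565), and the list passed without sirEGFP 3 (0.0265). With oligo 1 this list was called lower (median -0.25, adjusted p = 0.00425, and adjusted p = 0.0657 with an estimated correlation), with Eri1 (-0.72), Slbp (-0.58) and Cpsf2 (-0.56) as its 3 calls of 13, or 5 lower and 1 higher adjusted over the list alone. That list call was lost without sirEGFP 1 (0.0744) or the 3 arrays at the axis ends (0.207), and Eri1 without sirEGFP 2 (0.0513) or those 3 (0.0683). With oligo 1, Cpsf2 was lost without every array but Mock 1 and oligo 1 array 2 (0.0553 to 0.243), and Slbp without every array but sirEGFP 1, oligo 1 array 2 and oligo 2 arrays 1 and 2 (0.0505 to 0.184).

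Of 8 replication-independent histones (median 0.084, adjusted p = 0.290) limma called 0 in the mean comparison, also adjusted over the list alone, with 1 at an unadjusted p under 0.05. Macroh2a1 stood at 0.59 (adjusted p = 0.195), H2ax at 0.31 (0.441), Macroh2a2 at -0.28 (0.379) and H2aj at 0.15 (0.654), and Macroh2a1 passed without oligo 1 array 2 (0.0214). With oligo 2 the list was called higher (median 0.22, adjusted p = 0.00853, and adjusted p = 0.205 with an estimated correlation), with Macroh2a1 (1.14) and H2az2 (0.61), the latter named after its values were seen, as its 2 calls of 8, as many adjusted over the list alone, while with oligo 1 it was not called (median 0.023, adjusted p = 0.338). That list call was lost without sirEGFP 1 (0.0753), and Macroh2a1 without sirEGFP 2 and 3 (0.101 and 0.103) and oligo 2 arrays 1, 2 and 3 (0.101, 0.0515 and 0.0628). H2az2 was lost there without sirEGFP 1, 2 and 3 (0.0730, 0.0630 and 0.175), oligo 1 array 3 (0.0551) and oligo 2 arrays 1, 2 and 3 (0.172, 0.105 and 0.0592).

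Of 32 translation factors (median -0.064, adjusted p = 0.181) limma called 0 in the mean comparison, also adjusted over the list alone, with 2 at an unadjusted p under 0.05. They were led by Eif5 (-0.30, 0.228), Eif3f (0.25, 0.287), Eif1ax (-0.18, 0.465) and Eif4e (-0.18, 0.503), and the list passed without sirEGFP 3 (0.0152). With oligo 1 the translation list was called lower (median -0.058, adjusted p = 0.0434, and adjusted p = 0.360 with an estimated correlation), with 2 calls of 32, as many adjusted over the list alone, Eif5b (-0.66), named after its values were seen, and Eif5 (-0.55). That list call was lost without sirEGFP 1 (0.373), oligo 1 array 2 (0.560) or the 3 arrays at the axis ends (0.613, with a median of 0.031). Eif5b was lost without sirEGFP 2 and 3 (0.0513 and 0.0880), oligo 1 arrays 1 and 3 (0.0826 and 0.0592) or those 3 (0.216). With oligo 1, Eif5 was lost without Mock 1 and 2 (0.0521 and 0.0504), sirEGFP 2 and 3 (0.153 and 0.172), oligo 1 arrays 1 and 3 (0.142 and 0.116), oligo 2 array 3 (0.0533) or those 3 (0.113).

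In the integrated stress response (median -0.035, adjusted p = 0.168), Ddit3, the stress factor CHOP, rose by 0.57 and the transfer RNA ligase gene Nars fell by 0.57, 1 of 23 each way, or 1 and 2 adjusted over the list alone. Psat1 (-0.44, adjusted p = 0.191) and Cebpg (-0.42, 0.128) did not pass. The list passed without sirEGFP 3 (0.00268) or oligo 1 array 1 (0.0251). Nars was lost without sirEGFP 1 and 2 (0.0596 and 0.131) and Ddit3 without sirEGFP 2 and 3 (0.105 and 0.120), while Cebpg passed without oligo 1 array 2 (0.0178).

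Limma called 0 of 20 endoplasmic reticulum chaperones, also adjusted over the list alone, with 1 at an unadjusted p under 0.05. Their median was -0.014, their mean 0.021, and the test pointed down (adjusted p = 0.950). Sel1l stood at 0.35 (adjusted p = 0.278), Hyou1 at 0.33 (0.520), Pdia6 at -0.21 (0.582) and Manf at -0.17 (0.568). In glycolysis and hypoxia (median 0.13, adjusted p = 0.811) Bnip3, a mitochondrial protein of hypoxia, fell by 0.89, 1 of 19, with 1 higher and 1 lower adjusted over the list alone. Vegfa (0.56, 0.117), P4ha2 (0.57, 0.258) and Ankrd37 (-0.14, 0.700) did not pass. Without oligo 1 array 2 Vegfa (0.0354) and P4ha2 (0.0242) passed, and without the 3 arrays at the axis ends the list passed (median 0.31, adjusted p = 0.0236).

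Markers of other cell types showed few calls. Adipocyte markers had a median of -0.026 with a mean of 0.080 and a test pointing up (adjusted p = 0.814). Their 1 call of 9, also adjusted over the list alone, was the fatty acid carrier Fabp4, which rose by 1.00, while Cd36 (-0.18, 0.446), Retn (-0.14, 0.787) and Lpl (0.12, 0.771) did not pass. Macrophage markers had a median of -0.0060 with a mean of 0.092 and a test pointing up (adjusted p = 0.634). Limma called 0 of 10, or 2 adjusted over the list alone, with 2 at an unadjusted p under 0.05. Cd68 stood at 0.71 (0.149), Csf1r at 0.43 (0.125), C1qa at 0.14 (0.784) and Adgre1 at -0.095 (0.792). Skeletal muscle (median -0.0027, adjusted p = 0.811), smooth muscle and myofibroblast (0.078, 0.247) and epithelial markers (-0.030, 0.477) had 0 limma calls among 10 each, also adjusted over the list alone. At an unadjusted p under 0.05 there were 2, 1 and 0 in that order.

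The leading members for skeletal muscle were Tnnt1 (0.30, adjusted p = 0.281), Myh1 (-0.25, 0.362), Des (0.18, 0.585) and Myod1 (-0.17, 0.671). For smooth muscle they were Actg2 (0.65, 0.129), Acta2 (0.47, 0.570), Mylk (0.16, 0.614) and Tpm1 (0.11, 0.727). For epithelium they were Cdh1 (-0.24, 0.452), Krt5 (-0.097, 0.841), Cldn4 (0.093, 0.852) and Krt19, at -0.045 (0.913) and 2.44e-05 under quantile normalization. Without oligo 1 array 2, Actg2 (0.0469) and the macrophage marker Cd68 (0.0476) passed. In all, camera called 12 of the 25 lists in the mean comparison (4 higher, 8 lower), of which 1, p53 targets, held with an estimated correlation. With oligo 1 it called 13 (3 higher, 10 lower), of which 3 held, and with oligo 2 it called 9 (5 higher, 4 lower), of which 1 held. In the mean comparison fry called p53 targets (adjusted p = 0.00329), inflammatory and NF-kB targets (0.00509) and interferon-stimulated genes (0.0260) as higher, and G2/M (0.0131), cholesterol synthesis (0.0170), ribosomal proteins (0.0171) and DNA damage (0.0262) as lower.

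**Figure D3:**
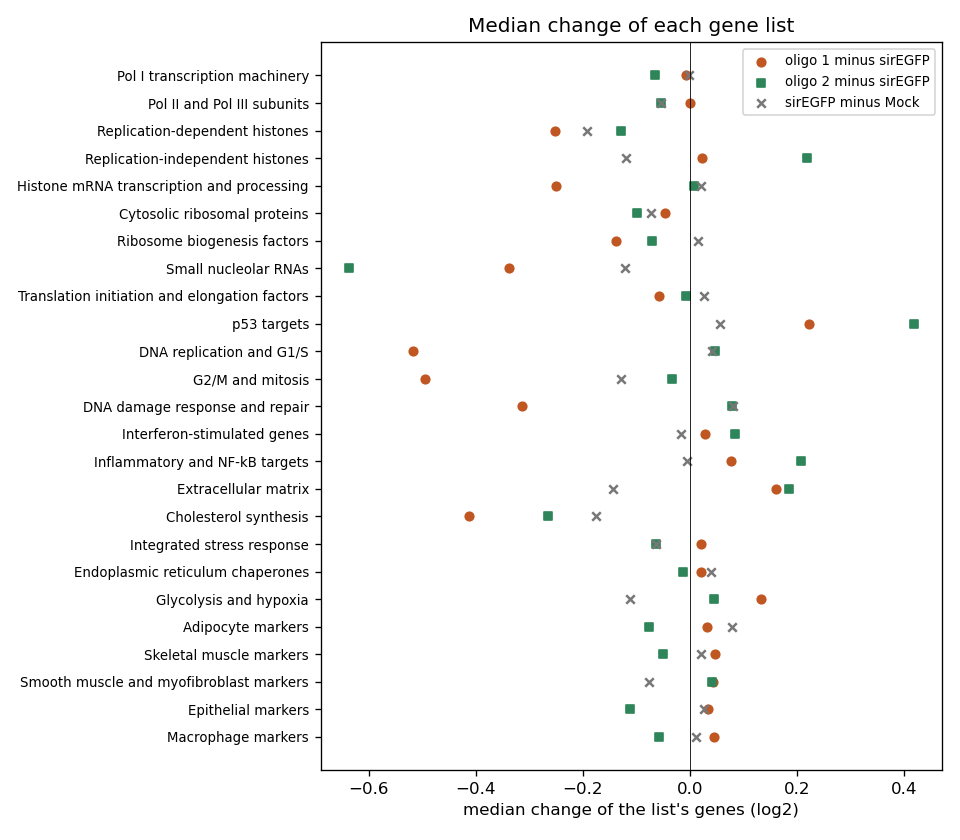
Median log2 change (x axis) of the genes of each of the 25 lists (y axis) with oligo 1 and oligo 2 against sirEGFP, and for sirEGFP against Mock. Medians of p53 targets lie at 0.22 and 0.42 with the siRNAs against UBF and at 0.056 between the controls, and those of the G1/S list lie at -0.52 and 0.048 with the siRNAs.

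Against Mock, 549 genes were called with oligo 1 (270 higher, 279 lower) and 848 with oligo 2 (585 higher, 263 lower), of which 152 were shared in the same direction and 1 in the opposite one, against 11.6 for independent lists. Both comparisons use the same 3 Mock arrays, from which part of this overlap may come, and no simulated count was made for it. Of the 80 genes shared against sirEGFP, 37 were also called in the same direction against Mock with both siRNAs. For oligo 1 against Mock the share of higher calls (49.2%) became 51.7% under quantile normalization, 58.4% without Mock 3, 56.3% with array weights and 54.5% with the axis as a covariate. Under median centring the share of higher calls for oligo 2 against Mock moved from 69.0% to 79.5%. The oligo 1 count was 293, 296 and 358 without Mock 1, 2 and 3, and 244 without oligo 1 array 3. The oligo 2 count was 307 and 374 without Mock 1 and 2, and 472, 400 and 342 without oligo 2 arrays 1, 2 and 3.

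Between the controls, limma called 0 genes for sirEGFP against Mock (smallest adjusted p = 0.123). At an unadjusted p under 0.05 there were 1247 genes, where 996.9 are given by chance. Without oligo 1 array 2 in the fit 1 gene was called, with array weights 2, both lower in sirEGFP, and with the within-group axis as a covariate 91, of which 20.9% were higher. Camera called 7 lists lower in sirEGFP with the preset correlation: replication-dependent histones (median -0.19), cholesterol synthesis (-0.18), extracellular matrix (-0.14), G2/M (-0.13), snoRNAs (-0.12), replication-independent histones (-0.12) and ribosomal proteins (-0.072). With an estimated correlation 0 held, at adjusted p = 0.176, 0.445, 0.734, 0.445, 0.817, 0.445 and 0.151 with an estimated correlation, in that order. Targets of p53 stood at 0.056 there (adjusted p = 0.305).

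The siRNAs also differed from each other, with 732 genes called in oligo 1 against oligo 2 (273 higher with oligo 1, 459 lower). Vip, a neuropeptide gene, was 2.60 higher on the log2 scale with oligo 1, Havcr2 1.82, the protein C receptor gene Procr 1.67, Ppef1 1.38 and P2ry10b 1.36. Lower with oligo 1 were Tnc (-2.58), Cd53 (-2.46), U90926 (-2.32), Dclk1 (-2.06) and the RNA sensor Tlr7 (-1.85). The SE of these 10 differences lay between 0.15 and 0.37. The share of calls higher with oligo 1 was 37.3% among the 732 and 23.2% among the 829 genes called under median centring. The 732 became 373 without oligo 1 array 3, and 451, 402 and 328 without oligo 2 arrays 1, 2 and 3. The difference in Procr was not called without oligo 1 array 3 (adjusted p = 0.0610) or oligo 2 array 2 (0.0611).

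Against sirEGFP, 209 genes were called with oligo 1 and not oligo 2 while their difference was called (58 higher, 151 lower). They included Ang2 (1.80), the haem oxygenase gene Hmox1 (1.56), Fbxo36 (1.48), Fetub (1.28) and P2ry10b (1.25), which rose, and Ncapg2 (-1.26), Cbx5 (-1.17), Mboat1 (-1.15), Gsdme (-1.13) and Rbmx2 (-1.12), which fell. With oligo 2 and not oligo 1 there were 189 (111 higher, 78 lower). Cd53 (2.88), Tnc (2.81), Dclk1 (2.25), Tlr7 (2.01) and the costimulatory gene Cd80 (2.01) rose, and Vip (-1.64), Ammecr1 (-1.54), Bnip3 (-1.53), Myct1 (-1.48) and Gpat3 (-1.37) fell. A second Cd80 probe set (mean level 5.85, against 5.94) stood at 0.73 with oligo 1 and 1.17 with oligo 2. The second, dimmer Gsdme probe set stood at -0.0049 with oligo 1 and -0.16 with oligo 2. That of Bnip3 (-0.24 and -1.21) went with the first. The differences between the siRNAs were not called for Hmox1 without Mock 3 (adjusted p = 0.0571), oligo 1 arrays 1 and 3 (0.112 and 0.167) and oligo 2 arrays 1, 2 and 3 (0.0551, 0.170 and 0.0602). The same held for Gsdme without oligo 1 array 1 (0.0591) and oligo 2 arrays 2 and 3 (0.109 and 0.0591), and for Mboat1 without oligo 2 arrays 1 and 3 (0.0597 and 0.0530).

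Beyond the cell cycle and DNA damage, camera called 4 more lists between the siRNAs. Histone processing genes had a median of -0.21, with 3 of 13 lower with oligo 1 (4 adjusted over the list alone) and adjusted p = 0.00343, and adjusted p = 0.0441 with an estimated correlation, which was lost whichever of the 12 arrays was left out (0.0501 to 0.106). Replication-independent histones stood at -0.28, with 2 of 8 lower (3 adjusted over the list alone), at adjusted p = 0.00148 and adjusted p = 0.103 with an estimated correlation. Targets of p53 stood at -0.072, with 5 of 28 lower, as many adjusted over the list alone, at adjusted p = 0.0133 and adjusted p = 0.187 with an estimated correlation. SnoRNAs stood at 0.25 (adjusted p = 0.00530, and adjusted p = 0.642 with an estimated correlation), and limma called 0 of 51, also adjusted over the list alone, with 10 at an unadjusted p under 0.05.

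**Figure D4:**
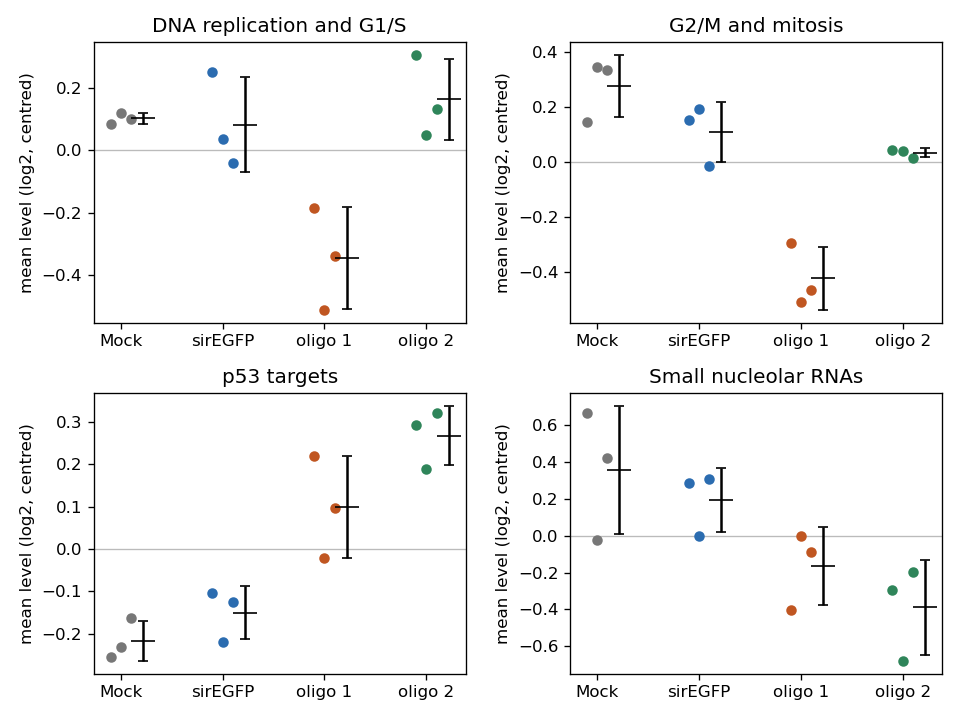
Mean level of the genes of 4 lists on each array (y axis, log2, each gene centred on its mean over the 12 arrays) in the 4 groups (x axis); points are arrays and black marks give the mean and SD of 3 arrays. In the G2/M list the oligo 1 arrays lie between -0.51 and -0.29 and the oligo 2 arrays between 0.02 and 0.05.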

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

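The list tests between the siRNAs, the tests along the within-group axis, of a scaled response, of the depth of the knockdown, of snoRNA host genes and of siRNA transfection, the use of both the preset and the estimated correlation, and all counts of other splits were chosen after the results had been seen.

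Between the siRNAs, 732 genes differed by limma's test of the difference itself. By the same test, log2 differences (oligo 1 minus oligo 2) were 2.60 for Vip, 1.82 for Havcr2, 1.67 for Procr, 1.38 for Ppef1, 1.36 for P2ry10b, 1.31 for Myct1, 1.27 for Bnip3, 1.27 for Hmox1, 1.14 for Ammecr1, 1.14 for Ang2, 1.02 for Fetub, 1.00 for Fbxo36 and 0.80 for Gpat3. They were -2.58 for Tnc, -2.46 for Cd53, -2.32 for U90926, -2.06 for Dclk1, -1.85 for Tlr7, -1.57 for Cd80, -1.25 for Rbmx2, -1.20 for Cbx5, -1.16 for Ncapg2, -0.96 for Gsdme and -0.82 for Mboat1. Against sirEGFP, the second probe sets of Cd80 (0.73 with oligo 1, 1.17 with oligo 2) and Gsdme (-0.0049 and -0.16) lay closer together. That of Bnip3 stood at -0.24 and -1.21. Dtna (1.27) and U90926 were called in opposite directions against sirEGFP, at 0.62 with oligo 1 and -0.64 with oligo 2 for Dtna, and at -1.29 and 1.02 for U90926. Dtna was named after its values were seen, as 1 of these 2 genes. Of the 6 arrays, 10 splits into 3 against 3 exist, too few for a share under 0.05, and 1 of them, the real one, gave 380 genes or more in a fit of these arrays alone, with 0 as the highest other. The 732 became 373 without oligo 1 array 3, and 451, 402 and 328 without oligo 2 arrays 1, 2 and 3.

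Lists that differed between the siRNAs with camera were G1/S (median -0.60), G2/M (-0.45), DNA damage (-0.33), replication-independent histones (-0.28), histone processing (-0.21), p53 targets (-0.072) and snoRNAs (0.25). Adjusted p with an estimated correlation was 0.0280, 0.0280, 0.0280, 0.103, 0.0441, 0.187 and 0.642 in that order.

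Cell cycle lists were lower with oligo 1 than with oligo 2, and the main axis of spread within groups holds 41.5% of that variance, with ends at oligo 1 array 2, oligo 1 array 1 and sirEGFP 1. Without these 3 arrays the G2/M list stayed lower with oligo 1 (median -0.48, limma's camera p = 0.0248 with an estimated correlation). The p of 0.0248 was not adjusted over the lists, so it does not show whether the call held. With all arrays, camera's unadjusted p for this list with an estimated correlation was smaller, at 0.0031. In the fit without the 3 arrays, the lone oligo 1 array left is assumed to vary like the others. The axis scores cancel within every group by construction, so this fit cannot decide whether that axis is a cause. A single response of all genes, only scaled deeper with oligo 1, stays open. With all arrays, 161 genes differed between the siRNAs and lay farther from 0 with oligo 2 against both controls. The thresholds allow 59.15 false ones (101.55 by an earlier bound), but such expected numbers do not cover genes that move together. Without the 3 end arrays the count stayed under the earlier bound, and the bound was lowered only after this failure had been seen. A deeper knockdown with oligo 1 cannot be told apart on Ubtf, where the siRNAs differed by 0.052 (95% interval -0.30 to 0.40). A biological effect of the knockdown and an effect of each siRNA's sequence apart from UBF were not tested against each other, since the siRNAs differ in sequence and both effects stay open.

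SnoRNAs were lower in the knockdown as a list, though their mean level on oligo 1 array 2 (-0.00037) lay above Mock 2 (-0.021) and sirEGFP 2 (-0.0034). The 20 host genes had a median of -0.049 (95% bootstrap interval over genes -0.13 to -0.021), short of the bound of -0.23 set from the snoRNA median. Snhg5 among them, named after its values were seen, fell by 0.66 (limma adjusted p = 0.00848, and 0.0702 without sirEGFP 3). The interval holds no spread between arrays, and transcript levels do not show host transcription, so lower output of host genes stays open as a cause. To weigh a lower yield of short RNAs, 17 other small non-coding RNAs were taken, with a median of -0.11 (-0.19 to -0.015), short of the same bound. The interval of the 17, likewise over genes, holds no spread between arrays. The set was not matched to the snoRNAs in length or signal, and dim members could not be told from absent ones. A lower yield of short RNAs therefore stays open, in whole or in part. The other small RNAs lay lower on all 6 knockdown arrays (-0.20 to -0.011) than on all 6 controls (0.0043 to 0.23). Rny3 (-0.76), Scarna8 (-0.58) and Rny1 (-0.46), none of which passed, lay near or below the snoRNA median. The list's call was lost with an estimated correlation (adjusted p = 0.141), so a spread between arrays shared by the snoRNAs stays open too.

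Targets of p53 were higher in the knockdown. A general effect of siRNA transfection, alike for every siRNA, would also act in sirEGFP, given at the same dose, and leave no difference from it. The list's mean level lay between -0.022 and 0.32 on the knockdown arrays and between -0.22 and -0.10 with sirEGFP. These levels do not overlap, which such an effect alone would not give, but they are the pattern itself and no separate test. The p that follows was lost without single arrays, so this explanation is not settled. The list's difference from sirEGFP had limma's camera adjusted p = 0.0304 with an estimated correlation. That p was 0.0531 without Mock 2, 0.134 without sirEGFP 1, 0.0765 without sirEGFP 2, 0.0602 without oligo 1 array 3 and 0.0535 without oligo 2 array 3. Without the 3 end arrays of the within-group axis the list stayed higher (median 0.27, limma's camera p = 0.00959 with an estimated correlation). The p of 0.00959 was not adjusted over the lists, unlike those before it, so it does not show whether the call held. With all arrays, camera's unadjusted p with an estimated correlation was smaller, at 0.00122. The fit without the 3 end arrays cannot decide whether the axis is a cause, since the axis scores cancel within every group by construction. The arrays left are also unbalanced along it. On the axis, sirEGFP 2 and 3 lie at 0.14 and 0.31, and oligo 1 array 3, the only one left, at -0.031. The oligo 2 arrays lie between -0.28 and 0.18. Spread along this axis stays open. An effect of the UBF knockdown stays a hypothesis, and effects of each siRNA's sequence stay open.

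Among the 1621 probe sets that list several genes, which no comparison above used, limma called 3 higher with both siRNAs, with 34 in the same direction at an unadjusted p under 0.05. Between the controls it called 0 of them, with 54 at an unadjusted p under 0.05. Of the 12102 probe sets without a gene name in the annotation used, limma called 0 with both siRNAs in the same direction, with 243 at an unadjusted p under 0.05.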

How the results depend on the processing

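The within-group axis as a covariate, the fit without its 3 end arrays, the limit for the correlation of the siRNAs, the list calls with an estimated correlation without each array and those of single siRNAs were chosen after seeing the data. All counts below come from limma, and unless a cause is stated, the cause was not tested. Each series of counts is given in the order oligo 1, oligo 2 and mean of both against sirEGFP, then oligo 1 and oligo 2 against Mock.

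Over all settings and left-out arrays, 225 of the values for whole comparisons stayed on the same side or within 1.5 times, 122 moved and 13 came to pass. Of values for named genes, 3382 stayed, 231 were lost, 137 came to pass and 11 changed sign. Of values for lists, 640 stayed, 20 were lost, 13 came to pass and 23 changed camera's direction. For the 9 list calls that hold with an estimated correlation, 61 values with 1 array left out held and 47 were lost, which these counts leave out, as they do the list calls of single siRNAs. Signal over background is not given by these values, so dim genes could not be told from absent ones, and the number of arrays limits the precision. A move of the correlation between the siRNAs beyond 0.0598, the SD with 1 array left out, was counted as a change.

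The replicate numbers were not taken as pairing the arrays. Of 18 pairs with the same number 12 correlated over 0.1, from -0.237 to 0.551, and 9 arrays correlated best with their own number, a hint from the data and not from the design. With the replicate number as a block the counts were 878, 773, 789, 838 and 1290, with 3 for sirEGFP against Mock, 184 shared and 159 shared with no common control, and higher calls made up 51.8% with oligo 1 against sirEGFP and 51.2% against Mock. With a random block they made up 50.4% of the latter. Ubtf stood at -0.55 (adjusted p = 0.0172) with oligo 1 and -0.61 (0.0115) with oligo 2. With a random block the first 3 counts were 746, 703 and 619, with 1 for sirEGFP against Mock, 148 shared and 138 with no common control, and Ubtf at -0.55 (0.0454) and -0.61 (0.0307).

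With all probe sets tested the counts were 244, 279, 163, 339 and 514, with 31 shared and 27 with no common control, where more tests enter the adjustment. Array weights gave 3814, 1180, 1949, 2695 and 1610, with 2 for sirEGFP against Mock, 3164 between the siRNAs, 559 shared and 366 with no common control, and Ubtf at -0.63 (adjusted p = 0.00178) and -0.61 (0.0204). The weight of oligo 1 array 3 was 8.92 there. With only the groups compared in the fit, which leaves fewer arrays for the spread, the counts were 101 for oligo 1, 236 for the mean, 276 for oligo 1 against Mock and 380 between the siRNAs, with 19 shared and 22 with no common control. At an adjusted p under 0.01 they were 159, 164, 108, 201 and 276, with 273 between the siRNAs, 14 shared and 15 with no common control, by the stricter threshold. A minimum change of 0.58 left 227 for the mean and 52 with no common control.

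With Mock as the control the counts were 848 for oligo 2 and 657 for the mean, with 152 shared and Ubtf at -0.74 and -0.79 (adjusted p = 0.0252 and 0.0146). With the mean of Mock and sirEGFP they were 753, 979 and 982, with 174 shared, a correlation of 0.390, and Ubtf at -0.64 (0.0185) and -0.70 (0.0114), where more control arrays enter. With an estimated correlation 1 list was called. The axis as a covariate gave 1707, 1438, 1561, 1464 and 2033, with 91 for sirEGFP against Mock, 1761 between the siRNAs, 469 shared and 316 with no common control, and Ubtf at -0.55 (0.0119) and -0.61 (0.00790). By construction it lowers the spread within groups and leaves the changes as they are. Without its 3 end arrays the counts were 255, 1049, 793, 145 and 1314, with 211 between the siRNAs, a correlation of 0.602 and 7 lists.

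No gene that changed sign, and no list for which camera's direction turned, had passed in the mean of both siRNAs against sirEGFP with all arrays. The median of interferon-stimulated genes, a list that had passed, turned to -0.0072 without the axis ends (adjusted p = 0.107), where camera's direction did not turn. Medians of lists that had not passed also changed sign in some settings, among them chaperones, skeletal muscle and macrophage markers under median centring and quantile normalization, and adipocyte markers under the latter. With oligo 1 alone, where translation factors had passed, their median turned to 0.031 without the axis ends. Glycolysis and hypoxia stood at 0.12 under quantile normalization, 0.13 without the dimmest genes, -0.057 against Mock and 0.042 against the mean of controls. Endoplasmic reticulum chaperones stood at -0.014 with all probe sets, 0.048 against Mock, 0.032 against the mean of controls, -0.014 with the axis as a covariate and -0.016 without its end arrays. Where these medians keep the sign given in the report, only camera's direction turned. Replication-independent histones stood at -0.052 against Mock. Krt19 stood at 2.44e-05 under quantile normalization, 0.11 against Mock and 0.031 against the mean of controls. Against Mock, Rrn3 stood at 0.093, Cd36 at 0.045, Myh1 at 0.0082, Cdh1 at 0.037 and Krt5 at 0.074. Without the axis ends, Pol II and Pol III subunits stood at 0.077, translation factors at 0.033, the integrated stress response at 0.0010, adipocyte markers at -0.084, Lpl at -0.034 and C1qa at -0.064.

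Leaving out each array in turn gave 155 to 863 genes for oligo 1, 198 to 627 for oligo 2, 108 to 722 for the mean, 244 to 674 and 307 to 1044 against Mock, 0 to 1 for sirEGFP against Mock and 328 to 833 between the siRNAs. Shared genes ranged from 20 to 140, and from 31 to 109 with no common control. Ubtf ranged from -0.71 to -0.39 with oligo 1 and from -0.76 to -0.44 with oligo 2, the correlation from 0.376 to 0.623, and lists called from 10 to 17. Among lists and genes whose direction turned, glycolysis and hypoxia ranged from -0.047 to 0.27, adipocyte markers from -0.080 to 0.024, chaperones from -0.028 to 0.016, skeletal muscle markers from -0.100 to 0.042 and C1qa from -0.022 to 0.24. Camera turned for glycolysis without sirEGFP 3 (-0.047), oligo 1 array 1 (-0.023) and oligo 2 array 1 (0.029), for adipocyte markers without sirEGFP 1 (-0.080) and oligo 1 array 2 (-0.034), and for chaperones without sirEGFP 2 (0.016), oligo 1 array 2 (0.0089) and oligo 2 array 2 (-0.012). For skeletal muscle markers it turned without oligo 2 array 3 (0.042), and C1qa changed sign without sirEGFP 1 (-0.022).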

Other observations

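The counts of other splits were chosen after the results had been seen.

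A prediction that abundant transcripts fall more than others in the knockdown was written before the test, and it was not borne out. Across genes, Spearman's rho between the Mock level and the change with the mean of both siRNAs was 0.0697, and 57 of the 84 splits of the 9 arrays gave a value as low. Genes are not independent replicates.

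Other splits of the same arrays, in fits of those arrays alone, bear on each count. For the 6 knockdown arrays as 1 group against sirEGFP, 4 of 84 splits gave 42 genes or more, the real one included. That share is under 0.05, but the highest other split gave 482. This other split, at several times the real count, set oligo 1 array 2, sirEGFP 2 and sirEGFP 3 against the rest. It points to a structure of the arrays other than the groups, from which the count cannot tell the knockdown. For the gene lists, 8 of 84 splits called 12 or more, with 15 as the highest other, so chance is not excluded for the number of lists called. For genes shared by both siRNAs, 100 splits were taken, the real one and others drawn at random from all that exist. Of these, 3 gave 54 or more, a share under 0.05, though the highest other drawn (66) went beyond the real one. With no control shared, 1 of 100 such splits, the real one, gave 82, with 0 as the highest other drawn.

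With 3 arrays against 3, the 10 splits are too few for a share under 0.05. For oligo 1 against sirEGFP, 2 splits gave 101 genes or more, and the highest other gave 887. It set oligo 1 arrays 1 and 3 and sirEGFP 1 against the rest, which again points to a structure of the arrays. For oligo 2 against sirEGFP 1 split, the real one, gave 359, with 0 as the highest other. Against Mock 1 split gave 276 for oligo 1 and 1 gave 1070 for oligo 2, each with 0 as the highest other. For sirEGFP against Mock all 10 splits gave 0, where limma with all arrays also called 0 and 1247 genes had an unadjusted p under 0.05.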
